A study of Rattus norvegicus with 8 samples.

How the data were processed

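Gene expression was measured in total RNA from the kidneys of male rats labelled as 10 weeks of age, sampled at day 28 after saline or after colistin at 30 mg/kg, with 4 samples per group. Per the labels, RNA was extracted with a column kit, amplified into cDNA, labelled with Cy3 and hybridised 1 sample per array. The labels number the samples within each group but do not say in words that each came from a separate animal, so the p-values measure the spread between these samples, part of which may be technical.

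The scanner values were spot intensities in linear units, deposited by the authors as 1 table per array and made with Agilent Feature Extraction 10.5, per the submitters' processing notes. Per the file headers, the processed intensity of each spot was already corrected for background and spatially detrended within its array, and it was not scaled between arrays. Flags for spots well above background, saturated spots and outlying spots were used as the same software wrote them. The deposited table of the whole series held log2 values, whose scale and centring no label or header stated. Set against the scanner values, differences between its columns correlated with those of log2 processed signal at 0.99986 or above across probes. Each column was shifted by about its array's 75th percentile, and each probe was centred on its median over the 8 arrays. The median log2 value of the deposited columns was 0.233, 0.0232, 0.0865 and 0.196 for saline arrays 1 to 4, and -0.113, -0.230, -0.0893 and -0.0327 for colistin arrays 1 to 4.

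Each array held 44254 spots, of which 42877 were not controls. Between 257 and 461 spots per array were left out as non-uniform or as outliers among copies of a probe, and no spot was saturated. Spots of a probe were averaged, which gave 30367 probes per array. The main values were log2 of the processed signal minus the array's 75th percentile over non-control probes. Probes were kept when they were well above background on at least 3 of 4 arrays of either group, which left 23718 probes.

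The scanner tables gave accessions and no gene symbols, so probes were named by matching RefSeq accessions, without versions, to a table of the rat assembly GRCr8. Of the 30367 probes, 18643 received a name, and these covered 15637 genes. The match named 18346 of 19481 probes with an NM accession, 262 of 3597 with an XM accession and 0 of 2082 with an Ensembl transcript ID. That table was used for names alone, since the array design used an older build, and no coordinates are given. Each gene was represented by its probe with the highest mean log2 signal over the 8 arrays, after 7 named probes with a missing value were left out. This gave 12411 genes. Among 2024 genes with over 1 kept probe, 0 had probes that passed the test in both directions. The probes of 4 of 39 changed genes with over 1 kept probe (Hnrnph1, Ier5, Sema5a and Spsb1) differed in the sign of their fold change.

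Colistin and saline were compared on the log2 scale with lmFit and eBayes in limma 3.58.1 under R 4.3.3. The test was two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Where no probe of a gene was well above background on any array of a group, and its own probe was on all arrays of the other group, the fold is given as a lower bound. The bound set the bright group's mean against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among probes well above background on that array. It is approximate, since probes not well above background can lie above that lowest value, and it leaves out the spread between arrays. The 40 gene lists, the test, the rule for named genes and all alternatives except those said to be added later were chosen before the data were examined. Each list was tested with limma's camera, a test of a list against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 40 lists. A correlation estimated per list, limma's fry, and an exact permutation of the 8 arrays on the median of each list were also run. For each list, the text gives how many members passed over all genes tested and how many passed when adjusted over the list alone.

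The named genes were the 12 largest rises and 12 largest falls among genes that passed, were well above background on at least 3 arrays of both groups and did not overlap between groups. To these were added up to 2 passing members per list and direction, up to 5 genes per direction with the largest lower bound, and a fixed group reported whatever its result. That group included Havcr1, Lcn2, Clu, Spp1, Timp1, Lrp2, Cubn, Slc15a2, Slc22a5, Slc34a1, Umod, Aqp2, Col1a1, Mki67 and Hmox1. Placeholder symbols were passed over. In all, the rule took 71 genes, of which 4 are not reported here.

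The file headers placed the arrays on 3 slides, each scanned as a batch and each holding both groups. Slide 1 held saline arrays 1 and 4 and colistin array 2, slide 2 held saline array 2 and colistin array 3, and slide 3 held saline array 3 and colistin arrays 1 and 4. Values were therefore also computed with slide as a block and within each slide. Other alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust, array weights, the deposited log2 values, a block on replicate number, and leaving out each array in turn. The normexp alternative had been planned on mean spot signals. It used the median spot and local background signals, the columns at hand. The scripts were tested on simulated data with 12411 genes, of which 200 were changed. They recovered 25% of genes changed by 2 log2 units and 71% of genes changed by 4, and of 107 calls 8 were unchanged genes and 3 were genes of the shifted lists. In that simulation 2 of 2 shifted lists and 0 of 38 unshifted lists were called. Its genes were drawn independently of each other, while the correlation estimated in the real lists was 0.077 in the median. The simulation therefore cannot show how often camera calls unshifted lists of correlated genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.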

Results

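Kidney transcripts were measured at day 28 in 4 samples from rats given saline and in 4 from rats given 30 mg/kg colistin. Colistin is a polymyxin antibiotic whose use is limited by injury to the renal tubule, and the comparison asks which kidney transcripts differed after it. The labels name the tissue as kidney, while the series title speaks of injured tubules, and no label states whether tubules were isolated. The saline arrays were dimmer. Their 75th percentile of processed signal lay between 156 and 197, against 271 to 317 on the colistin arrays. On saline arrays 69.3% to 75.8% of spots were well above background, and on colistin arrays 79.1% to 83.9%. The mean correlation across genes with the other arrays of the group was 0.777 to 0.826 for saline and 0.873 to 0.896 for colistin. The number of arrays limits the precision of every value.

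Colistin kidneys had higher levels of Havcr1 and Spp1 and lower levels of Egf, Pck1 and Pecam1 than saline kidneys. Havcr1, which encodes kidney injury molecule 1, rose by 4.48 ± 0.48 (log2 fold change ± SE, n = 4 per group), a 22.4-fold rise (adjusted p = 0.0063, limma with Benjamini-Hochberg adjustment). Spp1, which encodes osteopontin, rose by 5.70 ± 0.53 (adjusted p = 0.00374). Egf, which encodes the epidermal growth factor precursor made in the distal nephron, fell by 5.41 ± 0.59 (adjusted p = 0.00655), and Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, fell by 4.87 ± 0.47 (adjusted p = 0.00411). The endothelial adhesion molecule gene Pecam1 fell by 3.38 ± 0.41 (adjusted p = 0.0101).

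Of 12411 genes tested, 248 changed, with 181 higher and 67 lower after colistin, so that 73.0% of the changed genes were higher (limma, adjusted p under the threshold). With normexp background correction 3379 genes changed, 689 higher and 2690 lower, or 20.4% higher. Over probes well above background on all 8 arrays 121 were higher and 82 lower, or 59.6% higher. Each of the 248 genes changed by at least 2-fold, with a smallest absolute log2 fold change of 1.48 and a median of 3.28. The median log2 fold change of all genes tested was -0.14 in the main setting and -0.34 with normexp, and each list median has to be read against that shift. The 4 values of one group lay outside the range of the other in 18.6% of genes, where chance gives 2.86%. All 248 genes kept their sign within each of the 3 slides. This was largely fixed, since they were picked on these same arrays and a gene whose groups do not overlap has one sign on every slide. With slide as a block 40 genes changed (35 higher, 5 lower), 39 of them among the 248. Without colistin array 1, 2, 3 or 4 the count was 98, 106, 110 or 78, and 54 of the 248 genes passed in all 8 fits that left out 1 array. Without saline arrays 1 and 4 together, an alternative added after the data were seen because they lay at opposite ends of the second principal component, 143 genes changed (114 higher, 29 lower), and 86 of the 248 passed.

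**Figure D1:**
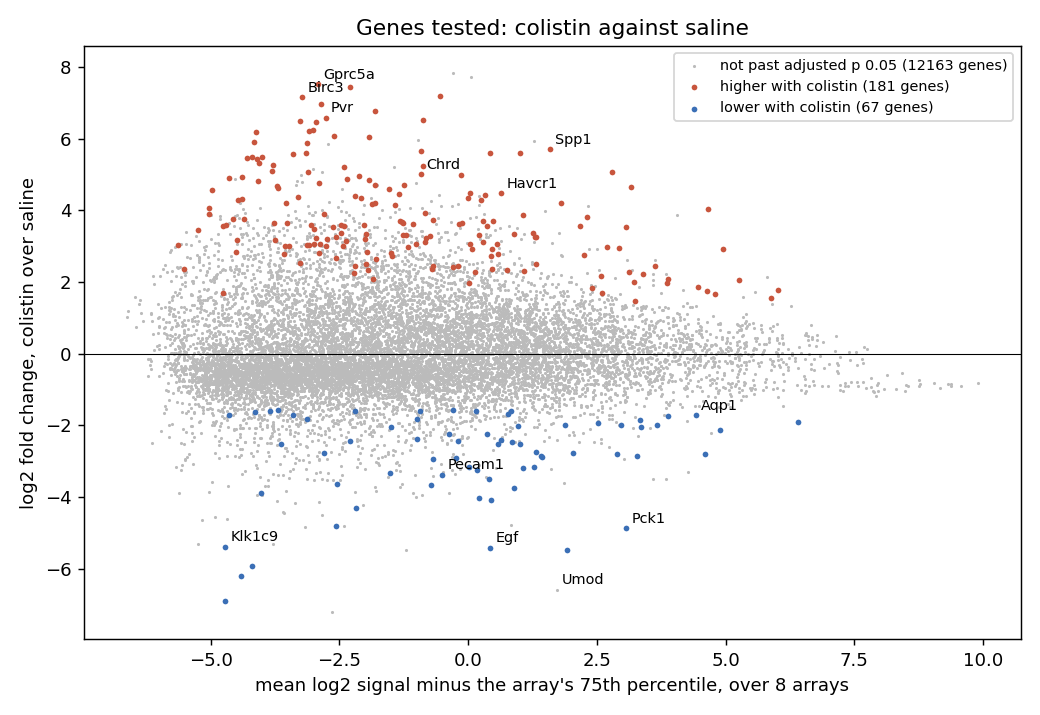
Each point is a gene, placed by its mean log2 signal over 8 arrays (minus the array's 75th percentile) and its log2 fold change, colistin over saline; coloured points passed the test (181 higher, 67 lower, limma with Benjamini-Hochberg adjustment). The dimmest, middle and brightest of 3 equal groups of genes held 58, 62 and 61 of the higher genes and 12, 16 and 39 of the lower ones, and Umod at -6.58 did not pass.

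The tubular injury markers shifted higher as a list, with a median log2 fold change of 2.14 over 20 genes tested (camera adjusted p = 4.1e-07; adjusted p = 0.128 with an estimated correlation). Of these 20 genes 6 rose and 0 fell, and 11 rose when adjusted over the list alone. Besides Havcr1 and Spp1, the calcium-dependent membrane binding protein gene Anxa2 rose by 4.64 ± 0.48 (adjusted p = 0.00571). The remaining risers were Lgals3, Gdf15 and Tnfrsf12a. Within slides 1, 2 and 3 the median of the list was 2.96, 1.46 and 2.77. Members fixed for reporting that did not pass included Lcn2, which encodes neutrophil gelatinase-associated lipocalin (1.49 ± 0.95, adjusted p = 0.365), Timp1, an inhibitor of metalloproteinases (2.14 ± 0.55, adjusted p = 0.0929), and Clu, which encodes clusterin (0.26 ± 0.67, adjusted p = 0.839). The estimate for Clu turned negative in some settings. Lcn2 differed widely between the colistin arrays, with an SD of 1.76. Genes of tubular dedifferentiation and repair had a median of 0.93 over 17 genes (camera adjusted p = 0.0127; adjusted p = 0.145 with an estimated correlation). None of the 17 passed over all genes, 5 rose when adjusted over the list alone, and without saline arrays 1 and 4 the list's adjusted p was 0.0822.

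**Figure D2:**
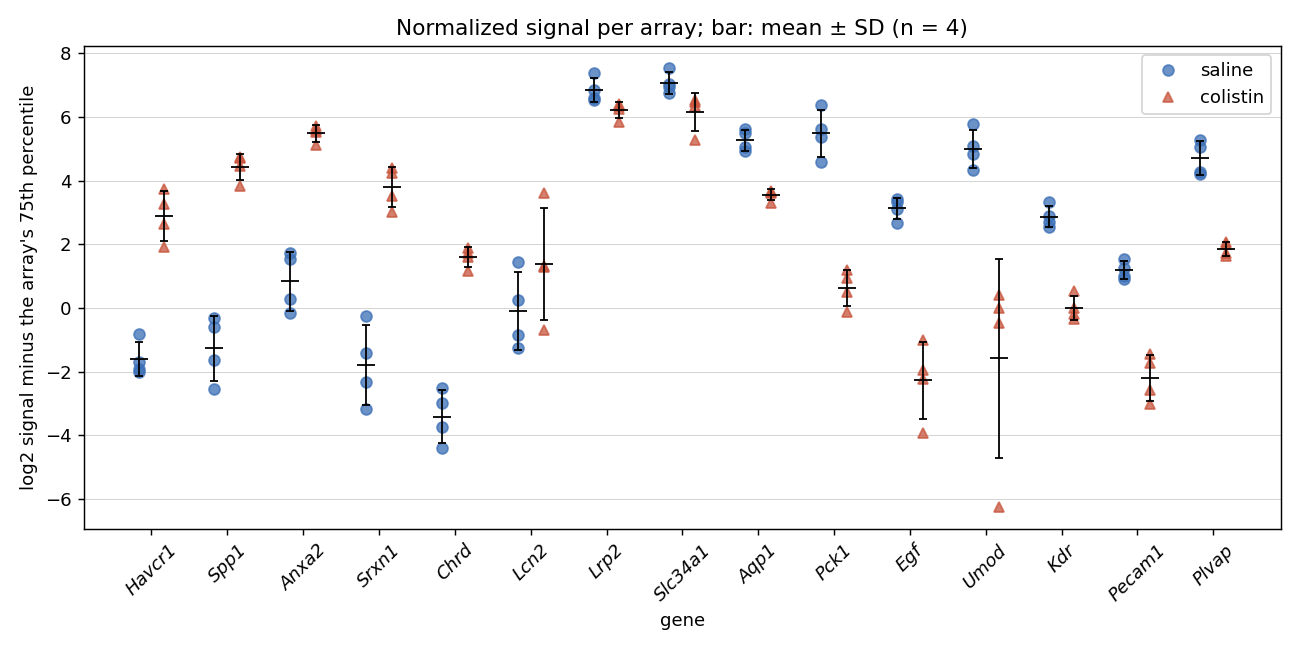
Normalized log2 signal (minus the array's 75th percentile) of 15 genes on each of 4 saline and 4 colistin arrays; points are arrays and bars are mean ± SD. Havcr1, Spp1, Anxa2, Srxn1 and Chrd were higher on every colistin array than on any saline array, while Lcn2 overlapped and 1 colistin array gave Umod at -6.24.

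Cldn3 and Cldn4, which encode tight junction claudins, rose by 7.18 ± 1.004 (adjusted p = 0.0153) and 5.08 ± 0.76 (adjusted p = 0.0198). Itgb4, the integrin beta 4 gene, rose by 6.52 ± 0.89 (adjusted p = 0.0151). The secreted metalloproteinase gene Adamts1 rose by 6.06 ± 0.54 and Chrd, which encodes the bone morphogenetic protein antagonist chordin, by 5.01 ± 0.45 (both adjusted p = 0.00321). Rises between 4.87 and 5.65 were found for Lhfpl2, the ubiquitin-like modifier gene Ubd, the adaptor gene Pik3ap1, Tmem43 and Mab21l3. Cldn3, Itgb4, Adamts1, Lhfpl2 and Mab21l3 were well above background on 3 of 4 saline arrays. Cldn3, Itgb4, Cldn4, Tmem43, Mab21l3 and Pik3ap1 lost their calls when some single arrays were left out, with adjusted p of up to 0.0523, 0.0514, 0.0616, 0.0735, 0.0616 and 0.0928. With slide as a block Adamts1, Spp1 and Chrd passed among the 12 largest rises, and the other 9 had adjusted p-values from 0.0557 to 0.096.

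Of the higher genes, 28 were well above background on all 4 colistin arrays and on no saline array, and 2 of the lower genes were the other way round. The largest bounds, which allow for background alone, were 133-fold for Gprc5a (adjusted p = 0.00067) and 95.8-fold for Pdpn, which encodes podoplanin (adjusted p = 0.00166). Birc3, an inhibitor of apoptosis, had a bound of 94.1-fold (adjusted p = 0.00013). Pvr, which encodes the poliovirus receptor CD155, had 88.0-fold (adjusted p = 0.00013), and complement factor I, Cfi, had 69.4-fold (adjusted p = 0.00321). All 5 passed in each fit that left out 1 array and with slide as a block. These bounds leave out the spread between arrays. The 95% intervals of the log2 fold changes of Gprc5a, Pdpn, Birc3, Pvr and Cfi began at 6.35, 5.72, 6.37, 5.92 and 4.93. The log2 bounds of these 5 genes were 7.06, 6.58, 6.56, 6.46 and 6.12. The lower genes were Tmprss13 and Klk1c9. Tmprss13, a serine protease gene, had a bound of 51.1-fold (adjusted p = 0.0371, and 0.103 at most with 1 array left out). Klk1c9 had a bound of 34.2-fold (adjusted p = 0.00699). The 95% intervals of their log2 fold changes reached up to -3.43 and -4.01, against log2 bounds of -5.68 and -5.095. Klk1c9 belongs to a family of near-identical kallikrein genes, so the target of its probe is uncertain.

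Among the largest falls outside the lists, Ppp1r1a, which encodes an inhibitor of protein phosphatase 1, fell by 5.47 ± 0.69 (adjusted p = 0.0116). Cby1, well above background on 3 of 4 colistin arrays, fell by 4.30 ± 0.76, Nlrp6 by 4.03 ± 0.80, Fpgs, which encodes folylpolyglutamate synthase, by 3.67 ± 0.52 and Myct1 by 3.62 ± 0.63. Their adjusted p-values were 0.0336, 0.047, 0.0154 and 0.0306, and with 1 array left out they reached 0.0867, 0.124, 0.053 and 0.0868. With slide as a block Egf, Pck1 and Slc26a4 passed among the 12 largest falls, and the other 9 had adjusted p-values from 0.067 to 0.157.

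Neither list of proximal tubule genes was called, and the members of each moved in both directions. The list of early-segment transporters had a median of -0.26 over 20 genes (camera adjusted p = 0.603), with 2 falls over all genes, and 3 rises and 4 falls when adjusted over the list alone. The water channel gene Aqp1 fell by 1.72 ± 0.29 (adjusted p = 0.0284) and the organic anion transporter gene Slc22a6 by 1.91 ± 0.33 (adjusted p = 0.0297). With 1 array left out these reached 0.0885 and 0.0919. Slc34a1, the sodium-phosphate cotransporter, gave -0.91 ± 0.38 (adjusted p = 0.208). Slc22a6, Slc34a1 and Slc13a3 (-1.45, adjusted p = 0.092) were the brightest members on saline arrays, and all had a negative fold change. Among the 20 genes 9 had a positive and 11 a negative fold change. The late-segment list had a median of 0.02 over 15 genes (camera adjusted p = 0.535), with 2 rises over all genes, and 3 rises and 2 falls when adjusted over the list alone. Its risers were the urate transporter gene Slc2a9 (4.20 ± 0.74, adjusted p = 0.0322) and Slc22a24, listed under its earlier symbol Slc22a19 (6.46 ± 1.18, adjusted p = 0.0369), and both lost their calls without most single arrays (adjusted p up to 0.0837 and 0.103). Slc22a24 was well above background on 1 of 4 saline arrays, so its fold rests on saline values mostly at background and its size is uncertain. On these same arrays the endothelial list had a median of -2.58 and the thick ascending limb list of -1.76.

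Receptor-mediated endocytosis is a route by which polymyxins enter tubule cells. Its list had a median of 0.48 over 13 genes (camera adjusted p = 0.625). It held 1 fall over all genes and 1 when adjusted over the list alone. That gene was the sorting nexin Snx3 (-1.93 ± 0.36, adjusted p = 0.0384; up to 0.113 with 1 array left out). The endocytic receptor genes Lrp2 (megalin) and Cubn (cubilin) gave -0.63 ± 0.31 (adjusted p = 0.265) and 1.25 ± 0.84 (adjusted p = 0.388). Polymyxin and organic cation transporters had a median of 0.40 over 14 genes (camera adjusted p = 0.479), with 1 rise over all genes, and 2 rises and 2 falls when adjusted over the list alone. The riser was the efflux pump gene Abcc2 (3.36 ± 0.58, adjusted p = 0.0306; up to 0.0917 with 1 array left out). The peptide transporter gene Slc15a2 gave 0.60 ± 1.23 (adjusted p = 0.791), a sign that turned in some settings, and was well above background on 3 of 4 saline arrays. The carnitine transporter gene Slc22a5 gave -1.83 ± 0.46 (adjusted p = 0.0886).

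All 4 lists of the distal nephron shifted lower by camera with the preset correlation. Intercalated cell genes had a median of -2.54 over 11 genes (camera adjusted p = 0.00246; adjusted p = 0.253 with an estimated correlation), with 1 fall over all genes and 6 when adjusted over the list alone. Slc26a4, which encodes the anion exchanger pendrin, fell by 3.33 ± 0.50 (adjusted p = 0.02; up to 0.0629 with 1 array left out). Thick ascending limb genes had a median of -1.76 over 13 genes (camera adjusted p = 0.0026; adjusted p = 0.253 with an estimated correlation), and 1 fell, or 3 when adjusted over the list alone. Relative to the saline means the median of this list was -4.26 on colistin array 1 against -1.28, -0.67 and -1.19 on the others, and without that array the list gave -1.20 (camera adjusted p = 0.00377). Its call over all genes was Egf. Umod, which encodes uromodulin, gave -6.58 ± 1.39 (adjusted p = 0.0586) and reached -5.03 (adjusted p = 0.00919) without colistin array 1, the array on which it was lowest and not well above background. Principal cell genes had a median of -1.43 over 12 genes (camera adjusted p = 0.00444; adjusted p = 0.208 with an estimated correlation), with 0 falls over all genes and 2 when adjusted over the list alone. On colistin arrays 1 to 4 this list had medians of -2.46, -1.57, -0.25 and -1.46, and the intercalated cell list of -4.05, -3.19, -1.15 and -0.81. The vasopressin-regulated water channel gene Aqp2 gave -2.94 ± 1.28 (adjusted p = 0.221). Genes of the distal convoluted and connecting tubule had a median of -1.24 over 11 genes (camera adjusted p = 0.0133; adjusted p = 0.19 with an estimated correlation), with 0 falls over all genes and 1 when adjusted over the list alone, and with normexp their adjusted p was 0.231. Relative to all genes the medians of these 4 lists, in the order given, were -2.40, -1.62, -1.29 and -1.10, and with normexp -1.23, -0.92, -0.70 and -0.10.

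Endothelial genes had a median of -2.58, and all 13 genes tested had a negative fold change (camera adjusted p = 6e-06; adjusted p = 0.128 with an estimated correlation). Of the 13, 4 fell over all genes and 8 when adjusted over the list alone. The vascular endothelial growth factor receptor genes Kdr and Flt1 both passed. Kdr fell by 2.87 ± 0.33 (adjusted p = 0.00801), Flt1 fell by 3.48 ± 0.65 (adjusted p = 0.0387; up to 0.104 with 1 array left out), and Plvap, a gene of endothelial diaphragms, fell by 2.85 ± 0.35 (adjusted p = 0.0101). Within slides 1, 2 and 3 the endothelial median was -2.89, -2.66 and -2.31, and with slide as a block Kdr, Flt1, Plvap and Pecam1 had adjusted p-values of 0.0633, 0.0899, 0.0512 and 0.0671. Podocyte genes had a median of -0.71 over 14 genes (camera adjusted p = 0.0133; adjusted p = 0.19 with an estimated correlation), with 1 fall over all genes and 2 when adjusted over the list alone. Podxl, which encodes podocalyxin of podocytes and endothelium, fell by 3.15 ± 0.51 (adjusted p = 0.0246; up to 0.0753 with 1 array left out). Vascular smooth muscle, pericyte and renin cell genes had a median of -0.85 over 12 genes (camera adjusted p = 0.00795; adjusted p = 0.145 with an estimated correlation), with 1 fall, or 3 when adjusted over the list alone. The fall was of the adhesion molecule gene Mcam (-3.88 ± 0.67, adjusted p = 0.0297; up to 0.0888 with 1 array left out), well above background on 2 of 4 colistin arrays, so its size is uncertain. Relative to all genes the endothelial, podocyte and smooth muscle medians were -2.44, -0.57 and -0.71, and with normexp -0.97, -0.25 and -0.36.

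Macrophage and monocyte genes had a median of -1.19 over 17 genes (camera adjusted p = 0.000593; adjusted p = 0.145 with an estimated correlation), with 1 fall over all genes, and 1 rise and 5 falls when adjusted over the list alone. The lysosomal protease gene Ctss fell by 2.01 ± 0.38 (adjusted p = 0.0428; up to 0.104 with 1 array left out). Genes of T and B lymphocytes had a median of -0.86 over 10 genes (camera adjusted p = 0.0196; adjusted p = 0.19 with an estimated correlation), with 1 fall and 1 when adjusted over the list alone. This was the coreceptor gene Cd4 (-1.59 ± 0.31, adjusted p = 0.0469; up to 0.126 with 1 array left out), and the list lost its call without saline array 1. Neutrophil genes had a median of -0.84 over 8 genes (camera adjusted p = 0.0322; adjusted p = 0.19 with an estimated correlation), with 0 falls over all genes and 0 when adjusted over the list alone, and lost the call without saline array 2 or 4 or colistin array 2 or 4. Erythrocyte genes had a median of -1.02 over 6 genes (camera adjusted p = 0.0259; adjusted p = 0.314 with an estimated correlation), with 1 fall, or 2 when adjusted over the list alone, and lost the call with normexp (adjusted p = 0.0682) and without saline array 2 or 4 or colistin array 3. The beta globin genes Hbb and Hbb-bs fell by 3.74 ± 0.60 (adjusted p = 0.0237) and 4.09 ± 0.78 (adjusted p = 0.0442). Their near-identical sequences leave the probes' targets uncertain, and with 1 array left out the adjusted p reached 0.0741 and 0.106. Genes of adipocytes and the adrenal cortex were not called (median -0.60 over 9 genes, camera adjusted p = 0.0514), with 0 calls over all genes and 0 when adjusted over the list alone. That list was called lower with normexp (adjusted p = 0.039), the mean of probes (0.0437), a replicate block (0.0431), and without saline array 3 (0.0225) or colistin array 3 (0.048). Relative to all genes the macrophage, lymphocyte, neutrophil and erythrocyte medians were -1.04, -0.71, -0.70 and -0.88, and with normexp -0.68, -0.29, -0.29 and -0.45.

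**Figure D3:**
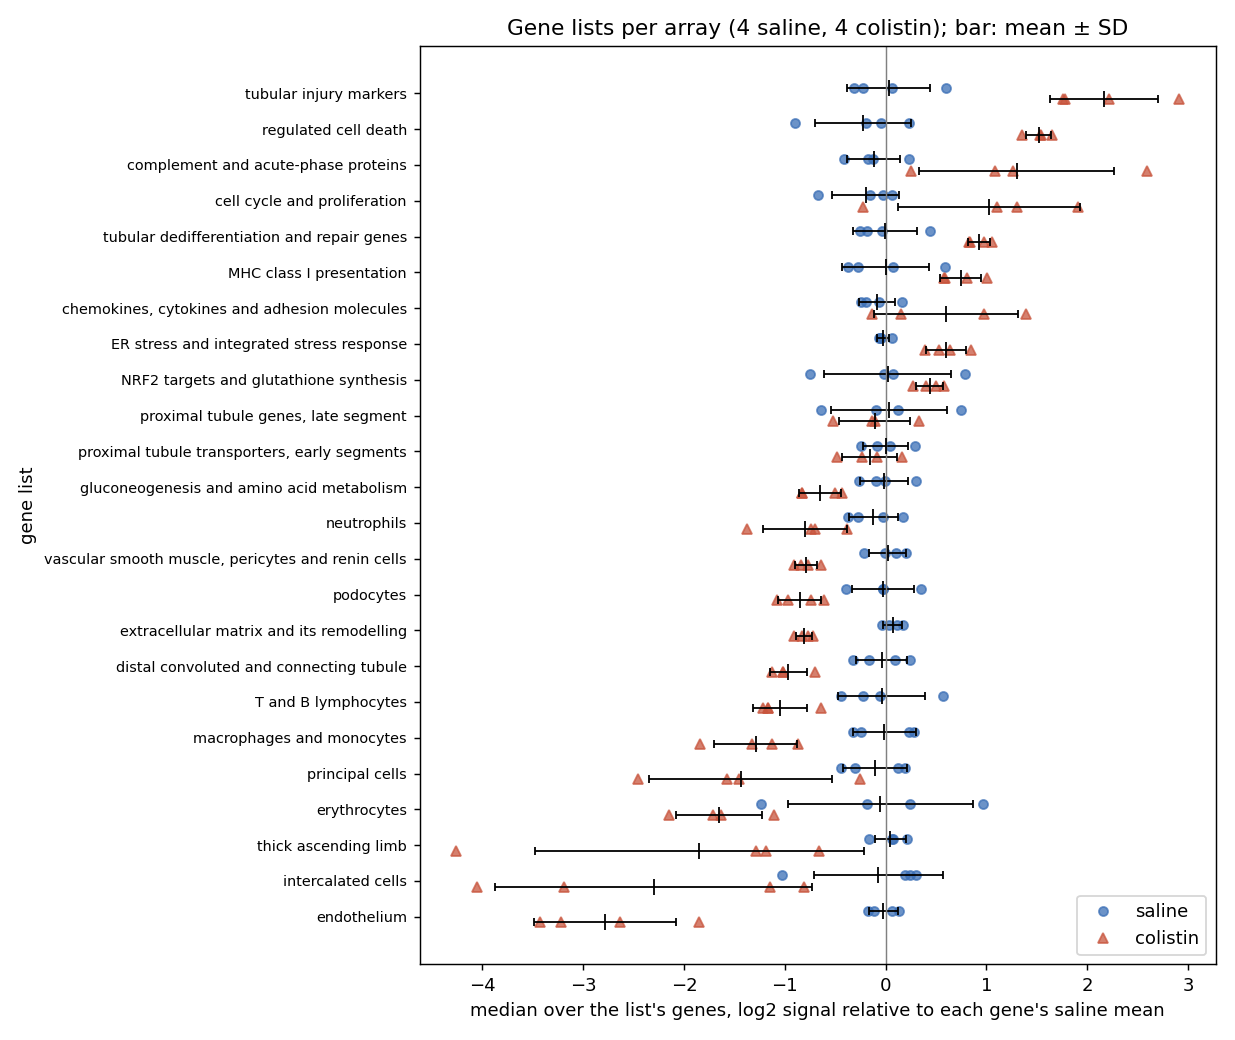
Median over the genes of each list on each array, in log2 signal relative to each gene's saline mean, for the 22 lists that shifted by camera and both proximal tubule lists; points are arrays (4 saline, 4 colistin) and bars are mean ± SD. Endothelial medians on the colistin arrays averaged -2.78 ± 0.71 and tubular injury medians 2.17 ± 0.54, while the proximal tubule lists overlapped between groups.

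Complement and acute-phase genes had a median of 1.61 over 19 genes (camera adjusted p = 0.00575; adjusted p = 0.19 with an estimated correlation), with 2 rises over all genes, and 7 rises and 2 falls when adjusted over the list alone. Besides Cfi, C4a rose by 3.57 ± 0.62 (adjusted p = 0.0309, and up to 0.0895 with 1 array left out). The fibrinogen genes Fga, Fgb and Fgg belong to this list and to the tubular injury markers, so the 2 lists are not separate evidence. Their log2 fold changes were 5.22, 7.83 and 2.15, and none passed over all genes. Genes of MHC class I presentation had a median of 0.62 over 14 genes (camera adjusted p = 0.00804; adjusted p = 0.19 with an estimated correlation), with 1 rise, or 3 when adjusted over the list alone. The peptide transporter gene Tap2 rose by 3.01 ± 0.59 (adjusted p = 0.046; up to 0.127 with 1 array left out). Chemokines, cytokines and adhesion molecules had a median of 0.83 over 22 genes (camera adjusted p = 0.0322; adjusted p = 0.249 with an estimated correlation), with 1 rise over all genes, which was Birc3, and 6 rises and 2 falls when adjusted over the list alone. Within slide 1 the median of this list was -0.14, against 0.52 and 0.80 within slides 2 and 3, and the call was lost with normexp (adjusted p = 0.0588) and without saline array 3 or 4 or colistin array 3 or 4. Relative to all genes the complement and chemokine medians were 1.75 and 0.97, and with normexp 0.98 and 0.11. Interferon-stimulated genes (median 0.47 over 19 genes, camera adjusted p = 0.221) had 0 calls over all genes, and 2 rises and 1 fall when adjusted over the list alone. Genes of MHC class II presentation (median -0.77 over 8 genes, camera adjusted p = 0.0782) had 0 calls over all genes and 2 falls when adjusted over the list alone, and their list was called lower with slide as a block (adjusted p = 0.0287), the mean of probes (0.0121), a replicate block (0.0482) and without colistin array 4 (0.0216).

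Genes of the extracellular matrix and its remodelling had a median of -0.64 over 26 genes (camera adjusted p = 0.0166; adjusted p = 0.145 with an estimated correlation), with 2 falls over all genes, and 1 rise and 7 falls when adjusted over the list alone. Relative to all genes this was -0.50, and -0.28 with normexp. Col1a2, which encodes a chain of type I collagen, fell by 2.94 ± 0.44 (adjusted p = 0.0198), and the metalloproteinase inhibitor gene Timp3 fell by 1.98 ± 0.38 (adjusted p = 0.0454). With 1 array left out these reached 0.0553 and 0.113. Col1a1, the partner chain of type I collagen, gave -0.50 ± 0.60 (adjusted p = 0.636). Genes of fibroblasts and TGF-beta signalling did not shift (median -0.06 over 20 genes, camera adjusted p = 0.935), with 0 calls over all genes, and 2 rises and 1 fall when adjusted over the list alone.

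Genes of regulated cell death shifted higher, with a median of 1.29 over 22 genes (camera adjusted p = 0.00045; adjusted p = 0.128 with an estimated correlation). Of these 1 rose over all genes and 7 when adjusted over the list alone. The p53 and DNA damage list had a median of 0.57 over 18 genes and was not called (camera adjusted p = 0.0514), with 1 rise over all genes and 1 when adjusted over the list alone. The list was called higher with normexp (adjusted p = 0.0214), median scaling (0.0483), no filter (0.018), the mean of probes (0.0034), array weights (0.0379), and without saline array 3 (0.0433) or colistin array 2 (0.0399). The gene that rose was Bbc3, the gene of the apoptosis inducer PUMA, at 6.08 ± 0.77 (adjusted p = 0.0116; 0.0547 with slide as a block). It was well above background on 2 of 4 saline arrays, so the size of its rise is uncertain. Cell cycle genes had a median of 0.85 over 21 genes (camera adjusted p = 0.0233; adjusted p = 0.19 with an estimated correlation), with 0 rises over all genes and 2 when adjusted over the list alone. Its median was -0.23 on colistin array 1, inside the saline range of -0.67 to 0.07, against 1.91, 1.30 and 1.11 on the others, and 2.66, 0.38 and 0.27 within slides 1, 2 and 3. The list lost its call without saline array 4 or colistin array 2 or 3, and its adjusted p was 0.0525 without saline arrays 1 and 4. The proliferation marker Mki67 gave 0.85 ± 1.11 (adjusted p = 0.664), negative without saline array 4. Relative to all genes the medians of the cell death and cell cycle lists were 1.43 and 0.99, and with normexp 0.71 and 0.28.

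NRF2 targets and glutathione genes had a median of 0.43 over 25 genes (camera adjusted p = 0.0259; adjusted p = 0.384 with an estimated correlation), with 2 rises over all genes, and 8 rises and 2 falls when adjusted over the list alone. The sulfiredoxin gene Srxn1 rose by 5.59 ± 0.65 (adjusted p = 0.00846), and the other riser was Abcc2 (3.36 ± 0.58, adjusted p = 0.0306). The heme oxygenase gene Hmox1 gave 0.30 ± 0.45 (adjusted p = 0.706). The list lost its call without saline array 1 or colistin array 2. Genes of ER stress and the integrated stress response had a median of 0.60 over 20 genes (camera adjusted p = 0.0196; adjusted p = 0.145 with an estimated correlation), with 0 calls over all genes and 0 when adjusted over the list alone. Antioxidant enzymes (median -0.11 over 17 genes, camera adjusted p = 0.76) and heat shock proteins and metallothioneins (median -0.08 over 14 genes, camera adjusted p = 0.906) had 0 calls over all genes and 0 when adjusted over the list alone.

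Genes of gluconeogenesis and amino acid metabolism had a median of -0.76 over 28 genes (camera adjusted p = 0.00548; adjusted p = 0.19 with an estimated correlation), with 1 rise and 2 falls over all genes, and 1 rise and 7 falls when adjusted over the list alone. With normexp this list was not called (adjusted p = 0.303), and its median relative to all genes went from -0.62 to -0.11, and to -0.41 with quantile normalization. Besides Pck1, the glucose-6-phosphatase gene G6pc1 fell by 2.81 ± 0.55 (adjusted p = 0.046; up to 0.119 with 1 array left out). Genes of fatty acid oxidation and peroxisomes were not called (median -0.40 over 32 genes, camera adjusted p = 0.251; lower without saline array 1, adjusted p = 0.0185), with 1 fall over all genes and 3 when adjusted over the list alone. Genes of oxidative phosphorylation and the citric acid cycle (median -0.20 over 35 genes, camera adjusted p = 0.337) had 0 calls over all genes and 0 when adjusted over the list alone. Genes of glycolysis and hypoxia (median -0.12 over 22 genes, camera adjusted p = 0.911) had 0 calls over all genes and 1 rise when adjusted over the list alone.

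Drug metabolism enzymes had a median near 0 over 21 genes (camera adjusted p = 0.772), with 1 rise over all genes, and 3 rises and 4 falls when adjusted over the list alone. The cytochrome P450 gene Cyp3a9 rose by 5.57 ± 1.08 (adjusted p = 0.0454; up to 0.105 with 1 array left out), but it was well above background on 1 of 4 saline arrays, so its fold rests on saline values mostly at background and its size is uncertain. Genes of cholesterol and fatty acid synthesis had a median of 0.40 over 23 genes (camera adjusted p = 0.0782; called higher with no filter, adjusted p = 0.019), with 1 rise and 1 when adjusted over the list alone, which was the squalene epoxidase gene Sqle (2.28 ± 0.39, adjusted p = 0.0297; up to 0.0898 with 1 array left out). Genes of autophagy and lysosomes had a median of 0.26 over 28 genes (camera adjusted p = 0.0656), with 1 rise, or 2 when adjusted over the list alone. This list was called higher with normexp (adjusted p = 0.00747), no filter (0.0142), the mean of probes (0.0437) and without colistin array 4 (0.0298). The riser was Gpnmb (3.05 ± 0.50, adjusted p = 0.0246; up to 0.0788 with 1 array left out; well above background on 3 of 4 saline arrays). The renin-angiotensin, vitamin D and phosphate hormone list had a median of -0.46 over 16 genes (camera adjusted p = 0.248), with 0 calls over all genes and 0 when adjusted over the list alone.

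In all, camera with the preset correlation called 22 of the 40 lists, 9 higher and 13 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.128. Fry, which tests whether the genes of a list move one way and does not compare them with other genes, called 22 lists, of which 19 were shared with camera. An exact permutation of the 8 arrays, added after the data were seen, gave the smallest p that 4 against 4 allows, 0.0286, for 16 lists and called 0 after adjustment. Among the 22 lists the medians per array overlapped between groups for principal cells, intercalated cells, erythrocytes, MHC class I, chemokines, cell cycle and NRF2 targets (unadjusted permutation p from 0.0571 to 0.257). With slide as a block 23 lists were called, and 21 of the 22 lists kept one sign within all 3 slides. The 22 were picked on these same arrays, which favours one sign. With normexp 4 of the 22 lost their call and 3 other lists gained one, and the median relative to all genes moved by over 1.5 times in 17 while keeping its sign in all 22. Over probes well above background on all 8 arrays 13 of the 22 were called, and the lists of neutrophils and erythrocytes were too small to test. Not called there were ER stress and lymphocytes (adjusted p = 0.0723 each), matrix (0.0601), smooth muscle (0.128), cell cycle (0.14), and chemokines and complement (0.19 each). The lymphocyte list was not called with no filter (adjusted p = 0.216), erythrocytes with the mean of probes (0.0513), nor chemokines with a replicate block (0.0705). The mean and median log2 fold change had opposite signs for heat shock proteins and metallothioneins, glycolysis and hypoxia, and drug metabolism enzymes.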

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

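The tests of quantile normalization, of the filter on all 8 arrays, of the cell type markers and of saline arrays 1 and 4 were chosen after the results were seen, while the counts over other splits of the arrays and the normexp test were set beforehand.

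In 15 of 226 groups of 4 values, 1 array lay far from the other 3 relative to the range of its group, where about 11.3 such groups arise by chance at 1 in 20. On colistin array 1 the normalized log2 signal was -2.79 for Aqp2 (the others 2.503 to 3.43), -3.002 for Ppp1r1a (the others -0.19 to 0.06), -1.73 for Slc22a24 (the others 0.73 to 1.12) and -6.24 for Umod (the others -0.47 to 0.40). On colistin array 4 it was 5.29 for Slc34a1 (the others 6.35 to 6.54), and the T and B lymphocyte list had a median of -0.64 (the others -1.22 to -1.16). On saline array 1 it was -0.59 for Clu (the others 1.32 to 1.58) and -1.83 for Cubn (the others 1.56 to 1.92), and the median of the ER stress list was 0.060 (the others -0.06 to -0.05). On saline array 3 it was -3.70 for Cyp3a9 (the others -7.28 to -6.87) and -2.71 for Slc22a24 (the others -7.59 to -7.20). On saline array 4 it was -0.32 for Hmox1 (the others -1.67 to -1.48), -7.08 for Mab21l3 (the others -4.15 to -3.90) and -4.64 for Slc2a9 (the others -3.73 to -3.58), and the intercalated cell list had a median of -1.02 (the others 0.19 to 0.30).

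Probes for which no gene name was found lie outside the comparison of genes. Of 9084 such probes that were kept, 78 changed (61 higher, 17 lower; limma with Benjamini-Hochberg adjustment over all kept probes), or 0.859%, against 272 of 14626 named probes, or 1.86%.

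The 8 arrays can be split into 4 and 4 in 35 ways. Only 1 split, the real one, gave as many as 248 changed genes, and the highest of the other splits gave 1. This argues against chance for the count of genes but cannot exclude it, since 1 in 35 is the smallest share possible. The other splits also hold the difference between saline and colistin as spread within their sides, which lowers their counts. For lists also only 1 split, the real one, gave as many as 22 shifted lists, but the highest of the others gave 20. That split set saline array 1 and colistin arrays 1, 2 and 4 against the rest, so it still parted 3 of 4 arrays of each group by treatment. Splits with 2 arrays of each group on either side gave 9 lists at most.

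More genes rose than fell (73.0% of 248), yet with normexp most changed genes were lower. A difference in distribution left in by the scaling is argued against, since quantile normalization, which gives every array one distribution, left 74.35% higher. It cannot restore signal lost near background. Every saline array was dimmer than every colistin array, so other effects of brightness cannot be told apart from the treatment. Transcripts lost below background on the dimmer saline arrays remain open. The share over probes well above background on all 8 arrays, 59.61% higher, cannot decide this, since that filter removes genes that rose from below background (83 of the 90 changed genes whose probe did not meet it were higher). The offset of normexp may account for its calls, since 1849 of its 2690 lower calls lay in the dimmest of 3 equal groups of genes, where the median standard error went from 0.61 to 0.19. Its shift of the median, lower by 0.27 log2 units in the dimmest than in the brightest group (value -0.2654), fell short of the 0.5 set beforehand, so this stays open.

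Most lists of markers of other cell types and distal segments were lower by camera with the preset correlation, and 0 were called with an estimated one. The list of fibroblasts and TGF-beta signalling did not shift (camera adjusted p = 0.935), and that of adipocytes and the adrenal cortex was not called (camera adjusted p = 0.0514). One equal loss of all material other than proximal tubule stays open. The endothelial list was lower than the podocyte list by more than the arrays varied (-1.932 log2, SDs 0.27 and 0.88, exact permutation p = 0.0286, the smallest possible). That p decides little, since the 2 lists were picked after the results were seen. Among the cell and segment lists called lower, they had the lowest and the least negative median (-2.58 and -0.71). The size of that gap depended on the setting. With normexp it was -0.54 (SDs 0.088 and 0.50, the same p), under the bound of 1 log2 unit, and within slides 1, 2 and 3 it was -3.03, -1.26 and -1.54. Taken from the median fold changes of the lists within slide 2, -2.66 and -1.76, it was also under that bound. With quantile normalization 13 of the 13 lower lists were also lower. This says little about scaling, since each list is compared with all other genes and a shift of a whole array cancels. The 13 also include the matrix and gluconeogenesis lists, which are not markers of cells or segments. With normexp the distal convoluted tubule, erythrocyte and gluconeogenesis lists lost their calls (camera adjusted p = 0.231, 0.0682 and 0.303), so an effect of processing stays open. A larger share of proximal tubule RNA stays open, since the median of the proximal lists lay at -0.05772 relative to all genes, between the bounds of 0.5 above and 0.5 below. A biological loss or down-regulation in these cells is also possible and was not tested.

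On the second principal component (20.6% of variance) saline array 4 lay at -109 and saline arrays 1, 2 and 3 at 96.3, 57.2 and 50.3, with the colistin arrays from -44.7 to -10.1. On the first (31.9%) saline array 4 lay at -149, the other saline arrays from -60.0 to -29.1 and the colistin arrays from 55.3 to 80.6. Saline arrays 1 and 4, at opposite ends of the second component, share a slide. Whether the slide played a part stays open. Their deviations from the saline mean correlated at -0.442 across genes, but this decides nothing, since the arrays were picked as lying at opposite ends. Different shares of proximal tubule in the samples may contribute, since between saline arrays 4 and 1 the proximal lists differed by 0.797 log2 (percentile 97.9 of 10000 random lists). The distal lists differed the other way by -0.31 but lay inside the range of random lists (percentile 5.84), so this stays open. No biological explanation was tested.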

How the results depend on the processing

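The fits without saline arrays 1 and 4, with every kept probe counted, and with exact permutation of lists were chosen after the results were seen. Main counts were 248 genes (181 higher, 67 lower) and 22 lists (9 higher, 13 lower). Quantile normalization (269 genes), median scaling (222), no filter (220), all-8 filter (203), the mean of probes (270), trend and robust (368, with 146 lower), array weights (311) and the deposited values (249) kept the total within 1.5 times. Normexp gave 3379 (689 higher, 2690 lower), 207 of the 248 among them, and 4 of the 248 turned sign. Slide as a block gave 40 (35 higher, 5 lower). Effects there were 0.988 times and standard errors 1.06 times the main ones in the median, and residual degrees of freedom went from 6 to 4. Replicate numbers did not pair the samples (correlations of deviations 0.000472, 0.00243, 0.0134 and -0.0205), and a replicate block, with 3 residual degrees of freedom, gave 5 genes (5 higher, 0 lower; 2252 at unadjusted p under 0.05) and 23 lists. Without saline arrays 1 and 4 there were 143 genes (114 higher, 29 lower). With every kept probe counted there were 350 (262 higher, 88 lower).

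With 1 array left out, genes ranged from 78 to 255, higher genes from 59 to 190, lower genes from 19 to 65, and lists from 18 to 23. Lower genes numbered 35, 27 and 31 without saline array 1, 2 or 3. Of the 71 named genes, 57 passed and 21 of these passed in all 8 such fits, 13 of them also with slide as a block. Calls were lost for 21, 22, 24 and 15 named genes without saline arrays 1 to 4, and for 32, 30, 28 and 31 without colistin arrays 1 to 4. With slide as a block 43 named genes lost their call, and with a replicate block 55. Fewer samples lower the power of each such fit.

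The all-8 filter left 38 lists and called 13 (5 higher, 8 lower). With normexp 21 lists were called, 18 of them among the 22, and the lists of the distal convoluted tubule, erythrocytes, chemokines and gluconeogenesis were not. An estimated correlation called 0 lists (0 higher, 0 lower), as did exact permutation. Among named genes, signs turned only for 3 that did not pass. The log2 fold change of Slc15a2 was -0.12 with normexp, -0.21 with array weights, -0.94 without saline arrays 1 and 4 and -0.41 without saline array 4. The log2 fold change of Clu was -0.081 with slide as a block, -0.23 without saline arrays 1 and 4, -0.26 without saline array 1 and -0.13 without colistin array 4. The log2 fold change of Mki67 was -0.16 without saline array 4. With 1 array left out, these 3 genes ranged from -0.41 to 1.51, -0.26 to 0.69 and -0.16 to 1.56. The cause was not tested. Signal over background limits the 29 changed genes below background on every saline array and the 4 on every colistin array. Of these, 28 and 2 have a bound, and the others have a fold of uncertain size.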

Other observations

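The bounds for all 4 tests in this part were set before their results were seen, but the genes that prompted them were noticed in the data. For the vacuolar proton pump, the rule that a value must clear its bound by more than the SD between arrays was applied after its value was seen, as was the choice of SDs relative to all genes. Permutation of medians relative to all genes was also added after the results were seen.

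Other members of the families of Anxa2, Cldn3 and Cldn4 went in different directions. S100a10, the binding partner of Anxa2, rose by 4.04 ± 0.33 (n = 4 per group, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00189), and is named here after its value was seen, as are Anxa1 and Cldn23. Of 9 other annexins 1 rose, Anxa1 (4.22 ± 0.70, adjusted p = 0.0257), and of 17 other claudins 1 rose, Cldn23 (5.26 ± 0.63, adjusted p = 0.00902, well above background on 1 of 4 saline arrays). None of 7 other S100a genes passed, although 5 had a positive fold change.

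One hypothesis was that these genes were part of a rise across their families. It may hold for the S100a genes, whose median log2 fold change lay 1.415 above that of all genes, and 0.90 above it with normexp, 1.30 with quantile normalization and 1.41 with median scaling. Their medians per array, taken relative to those of all genes, differed by 1.28 (exact permutation p = 0.0286, the smallest possible), but the p adjusted over 4 families by Benjamini-Hochberg was 0.0571. S100a6 and S100a11 are also among the tubular injury markers, S100a9 among the neutrophil genes and S100a4 among the fibroblast genes. For annexins the median lay 0.9904 above all genes. The exact permutation p was 0.0286 for medians per array relative to all genes but 0.0571 for the medians themselves, so this stayed open. For claudins the median lay below that of all genes (-0.4033, and -0.13 with normexp), and per array it differed by -0.27 relative to all genes (SDs 0.14 and 0.16, exact permutation p = 0.0571). This lies below the bound of 0.25 above all genes by more than those SDs, which argues against a rise across that family. Of its 17 genes 6 had a positive fold change. Cldn10, Cldn16 and Cldn19 (-0.84, -3.52 and -1.76) are also among the thick ascending limb genes, a list that was called lower.

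A second hypothesis was that the lower intercalated cell genes may be part of a fall of all vacuolar proton pump subunits. The 18 subunits outside that list had a median of -0.0979 relative to all genes, positive with normexp (0.09), and none passed the test. Not taken relative to all genes, their median per array differed between the groups by -0.35 (exact permutation p = 0.0286, the smallest possible; 0.0381 adjusted). Taken relative to all genes per array, it differed by -0.20 (SDs 0.14 and 0.12, exact permutation p = 0.0571). The relative median fold change lay short of the bound, set at 0.25 below all genes, by more than those SDs. It did not do so by more than 0.19, the colistin SD of medians not taken relative to all genes. The outcome thus rests on the choice of SDs, and a general fall stays open. The difference per array lay nearer that bound than its SDs, so a small fall is not excluded. The lowest subunit gave -1.17, against a median of -2.54 for the intercalated cell list.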
